A study of Mus musculus with 11 samples.

How the data were processed

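Total RNA of 11 mouse stomach samples was extracted with an AllPrep kit, labelled with biotin and hybridised to Affymetrix arrays, per the labels. The deposited values are 1 normalized log2 signal per probe set and sample, and the unit log2 was inferred from their range, which runs from 2.88 to 14.6. Affymetrix Expression Console is named in the submitters' processing notes; its version, algorithm and annotation are not given in the sources used here. Background correction and normalization set the level of dim probe sets, so small changes of dim genes depend on them most.

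The value table held 35556 probe sets. The platform annotation named 1 gene symbol for 21789 of them, several for 1621 and none for 12146, which are unnamed here. Of the 1-symbol probe sets, 21698 matched a mouse RefSeq gene (GRCm38.p6, used for names only) by gene number, and 0 symbols changed. Each gene took the probe set with the highest mean over the 11 arrays, which gave 19938 genes, 999 of them with more than 1 probe set. No dim gene was left out, and no calls of signal above background were used here. No coordinates are given, since no source names a build.

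Groups were taken from the labels. A model of group means was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so the 3 comparisons share an estimate of spread for each gene. P-values are two-sided with Benjamini-Hochberg adjustment over 19938 genes; genes passed at an adjusted p under 0.05. The sharing assumes like spread in all groups, and the median SD of a gene was 0.136 in NGE, 0.184 in pChePS_GC and 0.155 in pCP_GC. For 37 gene lists of stomach cell types, stroma, immune cells, pathways and tissue handling, camera was run with a preset correlation of 0.01, adjusted over the lists with at least 5 measured members; 0 of the calls held with an estimated correlation, where 9, 6 and 2 lists had an unadjusted p under 0.05 (pChePS_GC and pCP_GC against NGE, then between tumour groups).

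The designs, gene lists, alternatives and naming rule were fixed before the data were examined. Per comparison, the named genes are the floxed genes, the 6 largest rises and 6 largest falls among genes that passed with groups that do not overlap (leaving out predicted and non-coding gene models and antigen receptor segments), and up to 3 genes per list, with 5 genes per direction for the changes shared by both tumour groups. Snai2, Cd14, Hk2 and Fabp2 come from the lists.

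Before use, the tests were run on simulated arrays with 19938 genes, real means and spreads, and 200 changed genes. At 2-fold, 86% were recovered for pChePS_GC against NGE, 80% for pCP_GC against NGE and 72% for pChePS_GC against pCP_GC; at 1.5-fold the shares were 50%, 46% and 24%. False calls were 1.78%, 8.09% and 2.67% of calls, of which the share for pCP_GC against NGE (14 of 173) is above the 5% that the adjustment aims at. Each share comes from a single simulated set, so the shares do not rank the comparisons. Genes were drawn independently with the same spread in all groups, and far more genes passed against NGE in the data than the 200 changed here. Alternatives changed the variance prior, the groups fitted, the normalization, the filter on dim genes, the summary of probe sets, array weights, the replicate number as a block, the thresholds, the correlation in camera, camera on ranks, and the arrays, each left out in turn.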

Results

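Gene expression was measured on Affymetrix arrays in 11 samples of mouse stomach, 1 array per sample. The normal group (NGE) held normal gastric epithelium of 4 samples from mice without the Cre transgene. Gastric cancer tissue, labelled as diffuse type in both groups, came from mice in which Pdx-1-Cre recombines floxed alleles: 4 samples had 1 floxed and 1 wild-type allele of Cdh1 and floxed alleles of Trp53 and Smad4 (pChePS_GC), and 3 samples had floxed alleles of Cdh1 and Trp53 (pCP_GC). The array medians lay between 7.63 and 7.81 on the log2 scale, and the number of arrays limits the precision. Pairs of NGE arrays correlated at r = 0.990 to 0.994 across genes, pairs of pChePS_GC arrays at 0.962 to 0.978 and pairs of pCP_GC arrays at 0.972 to 0.988. The first principal component, which separated NGE from every tumour array, held 64.6% of the variance. The labels do not state that the samples of a group came from separate mice, so p-values measure the spread between these samples only.

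The floxed genes were examined first. Cdh1, which encodes E-cadherin, read 12.95, 12.94, 13.02 and 13.02 in NGE, 9.76, 11.07, 8.81 and 8.73 in pChePS_GC, and 12.02, 11.06 and 10.52 in pCP_GC. It fell by 3.39 on the log2 scale in pChePS_GC (SE 0.47, limma adjusted p = 0.000315) and fell by 1.78 in pCP_GC (SE 0.51, adjusted p = 0.0137), a call that was lost without pCP_GC replicate 3 (adjusted p = 0.0585, range over the alternatives 0.00154 to 0.0585). The difference between the tumour groups was -1.60 (95% interval -2.72 to -0.48, adjusted p = 0.183), and an exact two-sided permutation test of the 35 arrangements gave p = 0.143. Without pChePS_GC replicate 2 that difference, for Cdh1, pChePS_GC against pCP_GC, was -2.10 with an adjusted p of 0.0435 (range over the alternatives 0.0435 to 0.423). Smad4, a signal transducer of TGF-beta and BMP, read 11.09 ± 0.05 in NGE (SD, n = 4), 10.49 ± 0.40 in pChePS_GC (SD, n = 4) and 11.44 ± 0.05 in pCP_GC (SD, n = 3). It fell by 0.60 in pChePS_GC (adjusted p = 0.0152), and its change in pCP_GC was 0.35 (adjusted p = 0.114). The latter passed with only the 2 groups fitted (adjusted p = 0.00716), with array weights (adjusted p = 0.0224) and without pChePS_GC replicate 3 (adjusted p = 0.0245), which for Smad4, pCP_GC against NGE, lie in a range over the alternatives of 0.00716 to 0.492. The difference between tumour groups was -0.95 (adjusted p = 0.0585), and an exact two-sided permutation test gave p = 0.0571, where 0.0286 is the smallest possible. For Smad4, pChePS_GC against pCP_GC, it passed without pChePS_GC replicate 3 (adjusted p = 0.00704) and with array weights (adjusted p = 0.0215), in a range over the alternatives of 0.00704 to 0.296. Whether these probe sets lie in the floxed exons is not known here, so a level above background checks nothing about recombination. Trp53 was not analysed here.

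The sexes of the mice are not in the labels. Xist, the RNA that silences an X chromosome in female cells, read 12.24 ± 0.49 in NGE (SD, n = 4), 5.85 ± 0.14 in pChePS_GC (SD, n = 4) and 5.67 ± 0.13 in pCP_GC (SD, n = 3). The Y-linked gene Eif2s3y read 5.08 ± 0.10 in NGE, 10.27 ± 0.85 in pChePS_GC and 9.31 ± 1.06 in pCP_GC. Every comparison of tumours with NGE below therefore also compares arrays with opposite sex-linked levels, and the comparison between tumour groups does not.

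**Figure D1:**
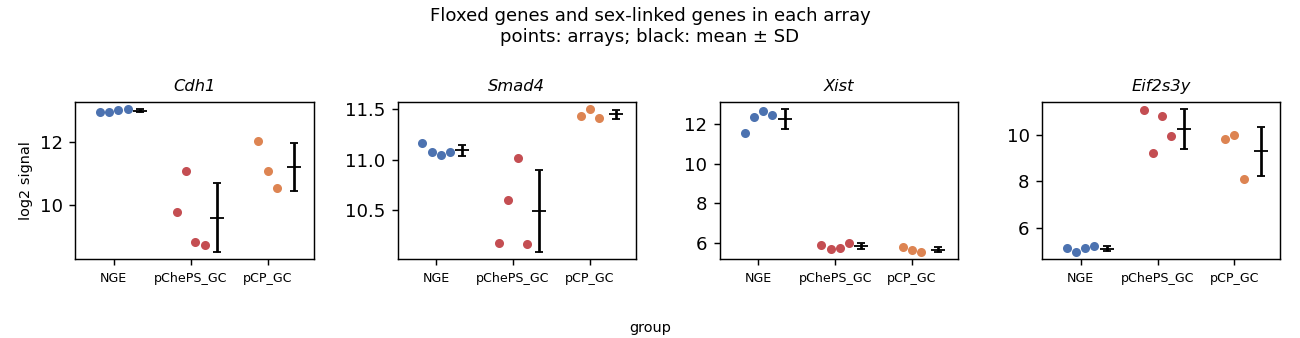
Log2 signal of Cdh1, Smad4, Xist and Eif2s3y on each array (points, coloured by group), with the group mean ± SD in black. Xist averaged 12.24 in NGE and 5.85 and 5.67 in the tumour groups.

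The comparison of pChePS_GC with NGE asks how tumours with floxed Smad4 and Trp53 and 1 floxed Cdh1 allele differ from normal epithelium. Atp4b, the beta subunit of the gastric proton pump, fell by 6.14 (SE 0.66), Chia1, an acidic chitinase of chief cells, fell by 6.44 (SE 0.76), and Gsdma2, a gasdermin, fell by 6.51 (SE 0.91). The secreted lectins Reg3g and Reg3b rose by 6.47 (SE 0.89) and 6.11 (SE 0.74), and the protease inhibitors Serpina3n, Timp1 and Serping1 rose by 5.48 (SE 0.42), 5.42 (SE 0.49) and 5.14 (SE 0.27). Pdia2 (-6.00) and Kcnj16, a potassium channel, (-5.66) fell as well. All of these had adjusted p at or below 0.000332 with 4 arrays in each group that did not overlap. For Reg3g, Reg3b, Timp1, Gsdma2, Pdia2 and Kcnj16, and for 36 of the 115 named genes that passed, the dimmer group lay under the 95th percentile of 1194 olfactory and vomeronasal receptor genes (7.24 in NGE and 6.99 in pChePS_GC), and where that level is background the change is a lower bound.

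Of 12 parietal cell genes 11 fell, among them Atp4a (-5.51) and Esrrg (-4.78), and the list shifted down (camera adjusted p = 9.56e-08, and adjusted p = 0.181 with an estimated correlation). Of 12 surface mucous genes 11 fell, among them Muc5ac (-4.84) and Psca (-4.81) (adjusted p = 5.42e-05, and adjusted p = 0.188 with an estimated correlation). Of 10 chief cell genes 8 fell, among them Cblif (-4.49) and Pga5 (-3.46) (adjusted p = 0.000707, and adjusted p = 0.181 with an estimated correlation). In the mucous neck and antral list 7 of 10 genes rose and 2 fell, with Cftr, a chloride channel, at 4.46 and Wfdc2 at 3.44 (adjusted p = 0.00352, and adjusted p = 0.182 with an estimated correlation). Adjusted over the list alone, 11, 12 and 9 genes fell in the parietal, surface mucous and chief lists. The sample titles name no region of the stomach, and a difference between the regions sampled was not tested. In NGE Muc5ac (14.22 to 14.29) and Atp4a (14.10 to 14.17) lay near the array maxima (14.37 to 14.56). Where signal saturates at that level their falls are lower bounds, which was not tested.

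In the fibroblast and collagen list 17 of 18 measured genes rose, with Lum at 4.99, Col12a1 at 4.90 and Tnc at 4.68 (adjusted p = 4.27e-14, and adjusted p = 0.182 with an estimated correlation). In the macrophage list 14 of 15 rose, with Lyz2 at 4.65, C1qb at 4.11 and Cd14 at 4.03 (adjusted p = 2.31e-12, and adjusted p = 0.182 with an estimated correlation). In the endothelium list 12 of 13 rose, with Emcn at 4.36 and Cdh5 at 4.21 (adjusted p = 1.99e-10, and adjusted p = 0.182 with an estimated correlation). In the matrix metalloproteinase list 11 of 14 rose, with Mmp7 at 4.79 and Mmp2 at 4.35 (adjusted p = 7.56e-09, and adjusted p = 0.181 with an estimated correlation). In the epithelial-mesenchymal transition list 10 of 15 rose, with Fn1 at 4.69 and Vim at 3.99 (adjusted p = 2.25e-07, and adjusted p = 0.188 with an estimated correlation). Of 24 measured proliferation genes 23 rose, by less, with Bub1 at 2.25 and Plk1 at 1.73 (adjusted p = 1.91e-11, and adjusted p = 0.188 with an estimated correlation). Adjusted over the list alone, 18 fibroblast, 14 macrophage, 13 endothelium, 12 metalloproteinase and 24 proliferation genes rose. The labels name epithelium for NGE and cancer tissue for the tumours. For these lists, and for the further lists called below in this comparison, a different share of cell types therefore cannot be told apart from a change within tumour cells. The same limit holds for the gastric cell lists above.

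Further lists also shifted up. Of 20 inflammatory cytokine and chemokine genes 9 rose (Il1a 4.87, Ptgs2 3.78), with an adjusted p of 2.54e-05 and adjusted p = 0.341 with an estimated correlation. Of 14 neutrophil genes 10 rose and 2 fell (Ltf 2.97, Cxcr2 2.80), with an adjusted p of 0.00011 and adjusted p = 0.218 with an estimated correlation. Of 12 smooth muscle genes 9 rose (Des 3.68), with an adjusted p of 0.000707 and adjusted p = 0.447 with an estimated correlation. Replicate 1 of pChePS_GC stood apart, with Des at 8.73 against 10.34 to 12.35 in the other pChePS_GC arrays. Its Cnn1 level of 7.78 lay near NGE (7.41 to 7.72). Of 12 TGF-beta targets 8 rose and 1 fell (Thbs1 4.41, Ccn2 4.18), with an adjusted p of 0.000706 and adjusted p = 0.188 with an estimated correlation. Of 14 EGF and HGF receptors and ligands 9 rose and 1 fell (Hgf 2.01), with an adjusted p of 0.0012 and adjusted p = 0.182 with an estimated correlation. Of 9 MHC class II genes 6 rose (Cd74 2.30), with an adjusted p of 0.0018 and adjusted p = 0.378 with an estimated correlation. Of 15 Wnt targets 5 rose (Cd44 4.18, Lgr5 1.69), with an adjusted p of 0.00312 and adjusted p = 0.188 with an estimated correlation. Of 12 catenins and other cadherins 6 rose and 1 fell (Cdh11 3.75), with an adjusted p of 0.00455 and adjusted p = 0.188 with an estimated correlation. Of 12 immune checkpoint genes 5 rose (Vsir 1.84), with an adjusted p of 0.00672 and adjusted p = 0.188 with an estimated correlation. Of 12 B and plasma cell genes 2 rose and 1 fell (Jchain 3.28), with an adjusted p of 0.0318 and adjusted p = 0.622 with an estimated correlation. The call of the B and plasma cell list, pChePS_GC against NGE, was lost without NGE replicate 2 (adjusted p = 0.0645), without pChePS_GC replicate 2 (adjusted p = 0.115) and without the dimmest 25% of genes (adjusted p = 0.182), the highest of a range from 0.00147 (ranges for lists leave out the estimated correlation, given beside each call). Without the dimmest 50% of genes the mucous neck, catenin, smooth muscle, Wnt and EGF and HGF lists lost theirs. Downward shifts were found for oxidative phosphorylation, where 16 of 19 genes fell (Ndufs1 -1.19, adjusted p = 2.51e-06, and adjusted p = 0.188 with an estimated correlation), and for BMP targets, where 8 of 12 fell and 1 rose (Id1 -1.93, adjusted p = 0.00312, and adjusted p = 0.182 with an estimated correlation). Adjusted over the list alone, 10 inflammatory genes rose, 18 oxidative phosphorylation genes fell, and the counts of the other lists in this paragraph did not change.

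The other lists did not pass. The adjusted p was 0.236 for gastric enteroendocrine cells (Ghrl -4.32 and Sst -3.38 passed singly), 0.654 for intestinal epithelium, 0.253 for pancreatic acinar cells, 0.654 for squamous epithelium (median -0.19 and mean 0.16, where the test pointed down) and 0.609 for epithelial keratins and junctions (7 rose and 5 fell of 20, with a median of -0.11 and a mean of 0.40 where the test pointed up). It was 0.611 for T and natural killer cells, 0.708 for mast cells, 0.509 for enteric neurons and glia, 0.652 for adipocytes, and 0.783 for mesothelium. It was 0.681 for p53 targets, 0.654 for interferon response, 0.117 for hypoxia and glycolysis and 0.62 for immediate early genes. The hypoxia and glycolysis list, pChePS_GC against NGE, passed without pChePS_GC replicate 2 (adjusted p = 0.0427) or 4 (adjusted p = 0.0321), in a range over the alternatives of 0.0321 to 0.641. The enteroendocrine list passed without the dimmest 50% of genes (adjusted p = 0.0248, the lowest of a range up to 0.518). Only 2 of the erythroid genes were measured, so that list was not tested.

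In all, 8386 of 19938 genes passed (3728 higher, 4658 lower), and at a change of at least 2-fold 1392 were higher and 665 lower. With each array centred on its median the split was 2695 higher and 9101 lower, since centring moved the median of all genes by -0.17. The 3988 dimmest genes had a median change of -0.17, and 1194 olfactory and vomeronasal receptor genes, which stomach is not known to use, had a median of -0.15.

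**Figure D2:**
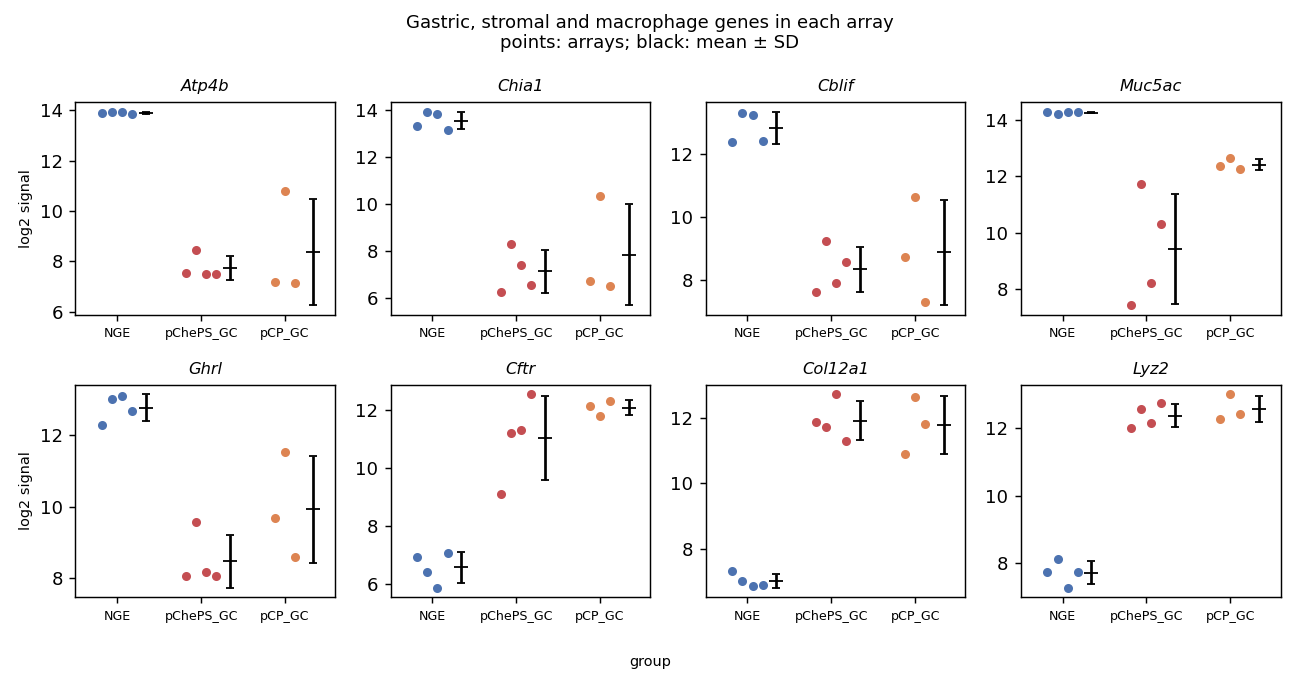
Log2 signal of 8 genes on each array (points, coloured by group), with the group mean ± SD in black. Atp4b, Chia1, Cblif, Muc5ac and Ghrl lie lower in every tumour array than in every NGE array, as for Atp4b at 7.14 to 10.79 against 13.86 to 13.93. Cftr, Col12a1 and Lyz2 lie higher in every tumour array.

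The comparison of pCP_GC with NGE asks the same of tumours with floxed Cdh1 and Trp53. Cftr rose by 5.50 (SE 0.62). The matrix proteins Aspn, Dcn and Tnc rose by 5.38 (SE 0.44), 5.14 (SE 0.32) and 4.97 (SE 0.61), and Kcne3, a potassium channel subunit, rose by 5.30 (SE 0.35). Atp4b fell by 5.52 (SE 0.72), Atp4a fell by 5.32 (SE 0.78), Chia1 fell by 5.72 (SE 0.82) and Kcnj16 fell by 5.41 (SE 0.28). All had adjusted p at or below 0.000464 with 3 tumour and 4 NGE arrays that did not overlap. The dimmer group of Cftr, Aspn, Tnc, Kcne3 and Kcnj16, and of 36 of 114 named genes that passed, lay under the same percentile of receptor genes (6.86 in pCP_GC), with the same limit. Among the pCP_GC arrays replicate 2 stood apart for 3 of the genes that fell, with Atp4b at 10.79 against 7.19 and 7.14, Chia1 at 10.32 against 6.70 and 6.49 and Atp4a at 11.40 against 7.57 and 7.48.

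Parietal cell genes (10 of 12 fell, adjusted p = 2e-06, and adjusted p = 0.196 with an estimated correlation) and chief cell genes (8 of 10 fell, adjusted p = 0.00331, and adjusted p = 0.196 with an estimated correlation) shifted down. Surface mucous genes did not pass as a list (adjusted p = 0.0638), with 3 of 12 falling, Capn9 by the most (-3.70). Muc5ac did not pass, although it read 12.27 to 12.64 in pCP_GC and 14.22 to 14.29 in NGE. The shared estimate of its spread takes in pChePS_GC, where its SD was 1.96. The count of 3 therefore depends on arrays outside this comparison, and its contrast with the count in pChePS_GC does not measure a genotype difference. The surface mucous (pit) cell list, pCP_GC against NGE, passed without pChePS_GC replicates 1, 2, 3 or 4 (adjusted p = 0.0289, 0.0209, 0.0313 and 0.0382), without pCP_GC replicate 1 (adjusted p = 0.0384) and without dim genes, in a range over the alternatives of 0.00179 to 0.19. Mucous neck and antral genes shifted up (7 of 10 rose, adjusted p = 4.78e-05, and adjusted p = 0.196 with an estimated correlation). For these gastric lists too a difference between the regions sampled was not tested. Pancreatic acinar genes shifted down (7 of 10 fell, Clps at -2.57, adjusted p = 0.012, and adjusted p = 0.397 with an estimated correlation). So did oxidative phosphorylation (15 of 19 fell, adjusted p = 5.82e-05, and adjusted p = 0.289 with an estimated correlation) and BMP targets (8 of 12 fell, while Bmp4 rose by 3.42, adjusted p = 0.0201, and adjusted p = 0.196 with an estimated correlation). Of the pancreatic acinar genes, Ptf1a (6.32 to 6.60) and Cela3b (6.60 to 6.72) lay under the receptor percentile of 6.86 in pCP_GC, while Clps was bright (9.85 to 12.61). For such dim members the small falls of dim genes described below are a limit.

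All 24 measured proliferation genes rose (Bub1 2.69, adjusted p = 6.45e-13, and adjusted p = 0.196 with an estimated correlation). So did 16 of 18 fibroblast and collagen genes (adjusted p = 1.95e-12, and adjusted p = 0.196 with an estimated correlation). Of the macrophage genes 14 of 15 rose (Lyz2 4.85, adjusted p = 3.76e-10, and adjusted p = 0.196 with an estimated correlation). Of the endothelium genes 12 of 13 rose (adjusted p = 5.87e-08, and adjusted p = 0.196 with an estimated correlation). So did 11 of 15 epithelial-mesenchymal transition genes (adjusted p = 7.75e-08, and adjusted p = 0.196 with an estimated correlation) and 12 of 14 metalloproteinase genes (adjusted p = 3.73e-07, and adjusted p = 0.196 with an estimated correlation). Here too a different share of cell types in cancer tissue than in epithelium cannot be told apart from a change within tumour cells. That limit holds for every list called in this comparison, in either direction. Upward shifts were also found for smooth muscle (9 of 12 rose, adjusted p = 0.000278, and adjusted p = 0.429 with an estimated correlation). Inflammatory cytokines shifted up too (8 of 20 rose, adjusted p = 0.00117, and adjusted p = 0.49 with an estimated correlation), as did MHC class II genes (6 of 9 rose, H2-Aa 3.22, adjusted p = 0.00117, and adjusted p = 0.397 with an estimated correlation). The same direction was found for TGF-beta targets (8 of 12 rose and 1 fell, adjusted p = 0.00133, and adjusted p = 0.196 with an estimated correlation) and Wnt targets (8 of 15 rose, Cd44 4.70, adjusted p = 0.00162, and adjusted p = 0.196 with an estimated correlation). EGF and HGF genes lay higher (8 of 14 rose and 2 fell, Hgf 2.87, adjusted p = 0.00357, and adjusted p = 0.196 with an estimated correlation), as did neutrophil genes (6 of 14 rose and 2 fell, adjusted p = 0.0169, and adjusted p = 0.49 with an estimated correlation) and catenins and other cadherins (5 of 12 rose and 1 fell, adjusted p = 0.0223, and adjusted p = 0.299 with an estimated correlation). Adjusted over the list alone, 17 fibroblast, 13 metalloproteinase and 9 EGF and HGF genes rose, 6 rather than 8 inflammatory genes rose, 9 chief cell genes fell, and the counts of the other lists called in this comparison did not change. The call of the neutrophil list, pCP_GC against NGE, was lost without pCP_GC replicate 3 (adjusted p = 0.0845, range over the alternatives 0.00413 to 0.0925). Without the dimmest 50% of genes the catenin, BMP, inflammatory and EGF and HGF lists lost theirs, and the catenin and neutrophil lists did so without the dimmest 25%.

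The other lists did not pass. The adjusted p was 0.205 for enteroendocrine cells, 0.799 for intestinal epithelium, 0.354 for squamous epithelium (median -0.26 and mean 0.016, where the test pointed down), 0.776 for epithelial keratins and junctions (median -0.18 and mean 0.25, where the test pointed up) and 0.403 for T and natural killer cells and for B and plasma cells. It was 0.284 for mast cells, 0.34 for enteric neurons and glia, 0.142 for adipocytes, and 0.799 for mesothelium (median -0.19 and mean 0.059, where the test pointed down). It was 0.703 for p53 targets (median -0.19 and mean 0.016, where the test pointed up). It was 0.356 for interferon response, 0.354 for hypoxia and glycolysis and 0.439 for immediate early genes. Immune checkpoint genes stood at 0.0706, and the immune checkpoint list, pCP_GC against NGE, passed without pChePS_GC replicate 4 (adjusted p = 0.0455), without pCP_GC replicate 1 (adjusted p = 0.0312) and after quantile normalization, in a range over the alternatives of 0.0201 to 0.139. The adipocyte list, pCP_GC against NGE, passed without pChePS_GC replicate 2 (adjusted p = 0.032, the lowest of a range up to 0.257). Enteroendocrine and hypoxia genes passed as lists without the dimmest 50% of genes (adjusted p = 0.0251 and 0.02, the lowest of ranges up to 0.298 and 0.544).

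In all, 10337 genes passed (3994 higher, 6343 lower), and at least 2-fold 1621 were higher and 564 lower. Centring the arrays gave 2686 higher and 9716 lower and moved the median of all genes by -0.21. The 3988 dimmest genes had a median change of -0.24 and the receptor genes one of -0.22.

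**Figure D3:**
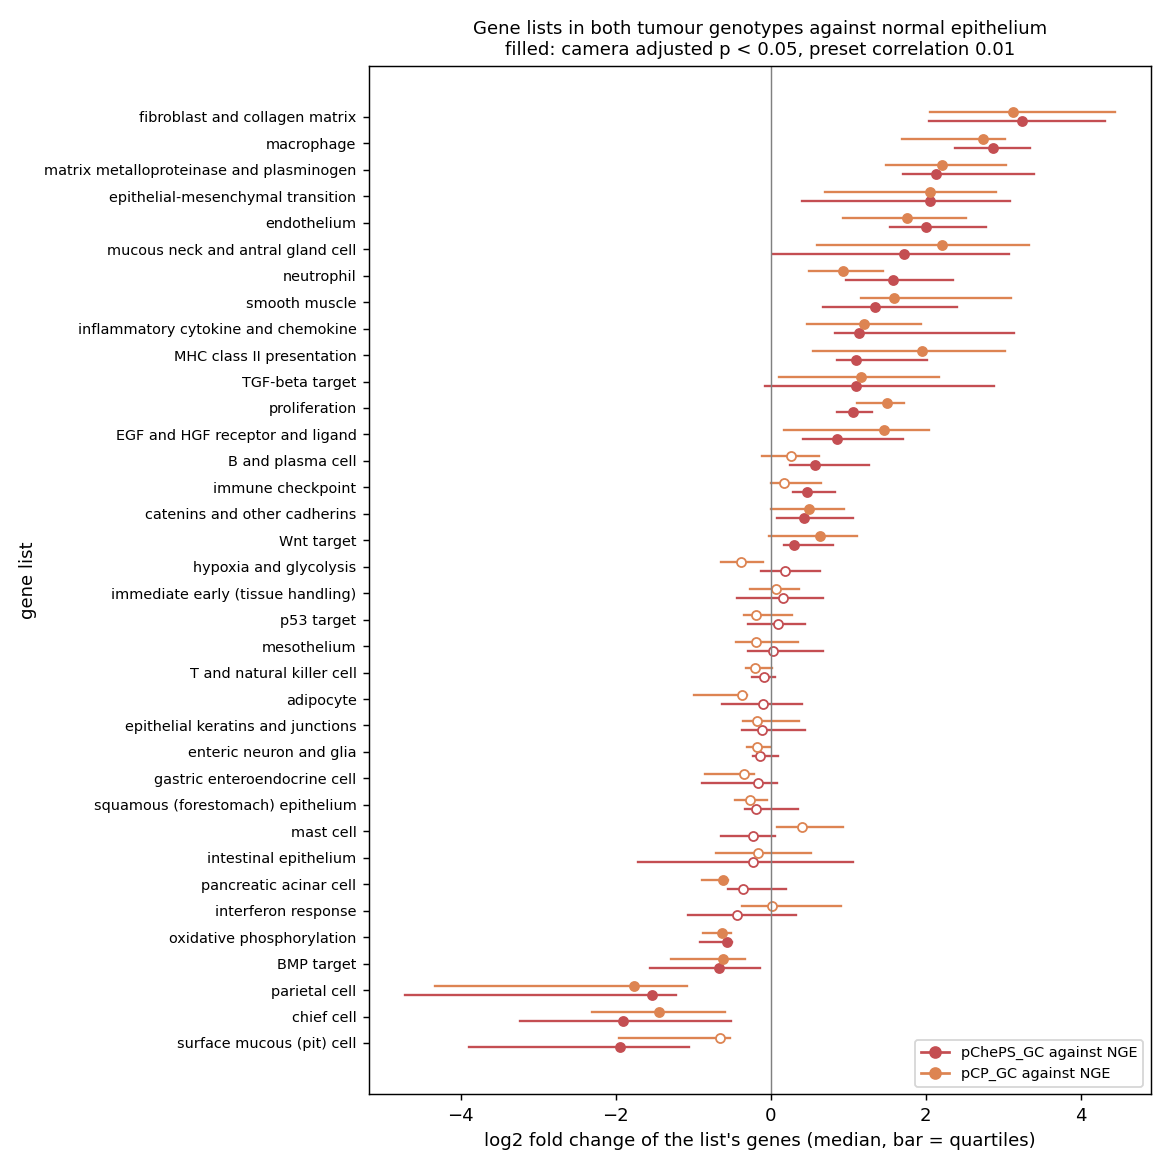
Median log2 fold change of each tested list (points; bars span the quartiles) in pChePS_GC and pCP_GC against NGE, filled where camera with a preset correlation of 0.01 gave an adjusted p under 0.05. The fibroblast and collagen list has the highest medians, 3.24 and 3.12.

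Serpina3n, Col12a1, Kcne3, Ccdc80 and Tnc rose, and Xist, Chia1, Pdia2, Atp4b and Kcnj16 fell, in both tumour groups. The fall of Xist goes with the opposite sex-linked levels of the NGE and tumour arrays. There were 3049 genes higher and 3855 lower in both and 2 in opposite directions, where independent lists of these sizes would share 746.8 and 1482, and at a change of at least 2-fold 1165 were higher and 463 lower in both. At an unadjusted p under 0.05 the shared genes were 3568 higher and 5137 lower, against at most 97 and 97 in 20 simulations of unchanged groups with the same controls. With adjusted p the simulations shared 0 by limma, where the test called at most 5 and 9 genes, so that this 0 sets no level for the overlap. Log2 fold changes correlated across genes, which are not independent replicates, at r = 0.917 against 0.20 in the simulations, and the covariance was 0.556 against 0.0082. With different NGE arrays for each comparison, over the 6 ways to split them, r was 0.873 to 0.910, the covariance 0.542 to 0.554, and the shared genes 1911 to 2097 higher and 1470 to 2661 lower, where independent lists would share 370.6 to 408 and 539.6 to 778.6. Independent lists, simulations and split controls all leave in place other differences from NGE that both tumour groups share. These are the sex-linked levels, cancer tissue against epithelium, and the small falls of dim genes. Of the 1194 receptor genes, 212 were called lower in pChePS_GC and 424 in pCP_GC.

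The comparison of pChePS_GC with pCP_GC asks how the tumour genotypes differ. Mmp7, a matrix metalloproteinase, was higher by 3.62 (SE 0.47, adjusted p = 0.0144), Arg1, which breaks down arginine, by 1.81 (SE 0.28, adjusted p = 0.0288), Hk2, a hexokinase, by 1.28 (SE 0.20, adjusted p = 0.0293), and Cd14, a monocyte receptor, by 1.24 (SE 0.12, adjusted p = 0.00484). Glp1r, the receptor of glucagon-like peptide 1, was lower in pChePS_GC (-3.66, SE 0.52, adjusted p = 0.0188). So were Bmp5 (-2.73, SE 0.30, adjusted p = 0.00665), Cyp21a1 (-2.15, SE 0.20, adjusted p = 0.00484) and Snai2, a repressor of E-cadherin (-1.12, SE 0.13, adjusted p = 0.00848). Ptprz1 (2.30), Ly6g2 (1.87), Trf (1.55) and Myo15b (1.49) were also higher, and Rgs13 (-3.30), Abi3bp (-2.41), Pga5 (-1.93) and Fabp2 (-1.82) lower. Snai2 read 6.87 to 7.12 in NGE, 6.75 to 7.18 in pChePS_GC and 7.88 to 8.32 in pCP_GC. In the same order Bmp5 read 6.95 to 7.62, 6.62 to 7.50 and 9.04 to 10.36. Cyp21a1 read 6.66 to 6.97, 6.58 to 6.76 and 8.18 to 9.23. For Snai2, Bmp5 and Cyp21a1 the difference lay mainly in a higher level in pCP_GC. Abi3bp lay above NGE in both tumour groups. Glp1r, Rgs13, Pga5 and Fabp2 lay below NGE in pChePS_GC. The pChePS_GC levels of Bmp5, Cyp21a1, Snai2, Rgs13 and Fabp2 lay under the 95th percentile of the receptor genes (6.99), so that their changes are lower bounds where this is background. In all 73 genes passed, 23 higher and 50 lower, of which 42 changed at least 2-fold, and 3294 had an unadjusted p under 0.05.

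Each of these 16 genes lost its call in at least 1 alternative. With only the tumour arrays fitted by limma, 0 genes passed and 2530 had an unadjusted p under 0.05. Cd14, Bmp5, Cyp21a1 and Snai2 passed whichever single array was left out. Mmp7 lost its call without pCP_GC replicate 3 (adjusted p = 0.0597), and over all alternatives its adjusted p ran from 0.000503 to 0.214. Glp1r lost its call without NGE replicate 3, pCP_GC replicate 1 or pCP_GC replicate 3 (adjusted p up to 0.0759), Trf without pCP_GC replicate 1 or 3 (up to 0.072) and Abi3bp without pCP_GC replicate 3 (0.0699). Hk2 lost it without any of the NGE arrays, pChePS_GC replicate 1 or pCP_GC replicate 1 (up to 0.0797), and Fabp2 without NGE replicate 1, 2 or 3, pChePS_GC replicate 1, or pCP_GC replicate 1 or 3 (up to 0.104). Arg1 lost it without any of the NGE arrays, pChePS_GC replicate 1, or pCP_GC replicate 1 or 3 (up to 0.0963), and Ly6g2 without any of the NGE arrays, pChePS_GC replicate 2, or pCP_GC replicate 1 or 3 (up to 0.101). Myo15b lost it without any of the NGE arrays, pChePS_GC replicate 1 or 4, or pCP_GC replicate 2 or 3 (up to 0.112). With 1 array left out, Rgs13 passed without pChePS_GC replicate 2 or pCP_GC replicate 2 and with no other array (up to 0.0888), Ptprz1 without pChePS_GC replicate 3 alone (up to 0.15) and Pga5 without NGE replicate 1 alone (up to 0.161). Over all alternatives the adjusted p of these 11 genes ran from 0.00154 (Trf) to 0.271 (Myo15b). Leaving out NGE replicates 1, 2, 3 and 4 in turn left 31, 33, 26 and 28 genes, although these arrays belong to neither tumour group. There were 30 without pCP_GC replicate 1, 31 without pCP_GC replicate 3 and 154 without pCP_GC replicate 2.

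As lists, surface mucous genes (median -0.87, adjusted p = 1.75e-06, and adjusted p = 0.747 with an estimated correlation) and proliferation genes (median -0.31, adjusted p = 1.75e-06, and adjusted p = 0.773 with an estimated correlation) lay lower. So did mucous neck and antral genes (median -0.63, adjusted p = 0.000631, and adjusted p = 0.592 with an estimated correlation), interferon response genes (median -0.45, adjusted p = 0.00191, and adjusted p = 0.838 with an estimated correlation) and mast cell genes (median -0.72, adjusted p = 0.00628, and adjusted p = 0.772 with an estimated correlation). Hypoxia and glycolysis genes (median 0.63, adjusted p = 9.34e-06, and adjusted p = 0.772 with an estimated correlation) and neutrophil genes (median 0.67, adjusted p = 0.001, and adjusted p = 0.772 with an estimated correlation) lay higher. Pancreatic acinar genes (median 0.36, adjusted p = 0.00574, and adjusted p = 0.772 with an estimated correlation) lay higher too. Among them Ptf1a and Cela3b lay under the receptor percentile of 6.86 in every pCP_GC array, where small changes depend most on background. Of the members of these lists Hk2 alone passed among all genes. Adjusted over the list alone, 7 surface mucous, 2 mucous neck and 1 proliferation genes were lower, 7 hypoxia and 3 neutrophil genes were higher, and 4 pancreatic acinar genes were higher and 1 lower, and no interferon or mast cell gene passed. Muc5ac, the main mucin of the stomach surface, was 7.99-fold lower (adjusted p = 0.136), and passed without pChePS_GC replicate 2 (adjusted p = 0.0229, the lowest of a range up to 0.318). The interferon response list, pChePS_GC against pCP_GC, lost its call without pCP_GC replicate 3 (adjusted p = 0.521, the highest of a range from 9.66e-07), as did the pancreatic acinar cell list, pChePS_GC against pCP_GC (adjusted p = 0.081, the highest of a range from 0.000216). Without the dimmest 50% of genes the interferon response list stood at an adjusted p of 0.299. The mast cell list, pChePS_GC against pCP_GC, lost its call without pCP_GC replicate 2 (adjusted p = 0.0976) and without the dimmest 25% of genes (adjusted p = 0.126, the highest of a range from 0.000395).

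The other 28 lists had adjusted p of 0.0547 to 0.983, and some passed without 1 array. Without pCP_GC replicate 2 the macrophage (adjusted p = 7.83e-07, range up to 0.899), endothelium (0.0389, up to 0.822) and metalloproteinase lists (0.0389, up to 0.886) passed as higher and the BMP target list as lower (0.0428, up to 0.358). The fibroblast and collagen list then passed as higher (median 0.43, adjusted p = 0.0389, range up to 0.966), against the downward direction of its test on all arrays. Without pChePS_GC replicate 1 the B and plasma cell (0.000415, up to 0.542) and adipocyte lists (0.0107, up to 0.577) passed as higher, as did the macrophage, endothelium and inflammatory lists, and the BMP list as lower. The smooth muscle list passed as lower without pChePS_GC replicate 2 or 3 or pCP_GC replicate 1 or 3 (lowest adjusted p 8.29e-05, up to 0.682), the MHC class II list without pChePS_GC replicate 2 (0.000536, up to 0.635), and the immediate early list without pChePS_GC replicate 3 (0.0362, up to 0.933), each as lower. The Wnt target list passed as lower without pChePS_GC replicate 4 (0.0176, up to 0.325), and the epithelial-mesenchymal transition list as lower without pCP_GC replicate 1 (0.0236, up to 0.974). The adipocyte list passed as higher without pChePS_GC replicate 4, the inflammatory list without pCP_GC replicate 3 (0.0406, up to 0.899), and the B and plasma cell list without pCP_GC replicate 2. Without dim genes the B and plasma cell (dimmest 25%), endothelium, macrophage and metalloproteinase lists (dimmest 50%) passed as higher. The test pointed down where the median was above 0 for fibroblast and collagen genes (median 0.10, mean 0.028), TGF-beta targets (0.031 and 0.097), enteroendocrine cells (0.13 and -0.11), intestinal epithelium (0.043 and -0.25), epithelial-mesenchymal transition (0.0084 and -0.023), oxidative phosphorylation (0.0040 and -0.0025) and immediate early genes (0.038 and -0.073). For p53 targets it pointed down with a median of -0.070 and a mean of 0.025.

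**Figure D4:**
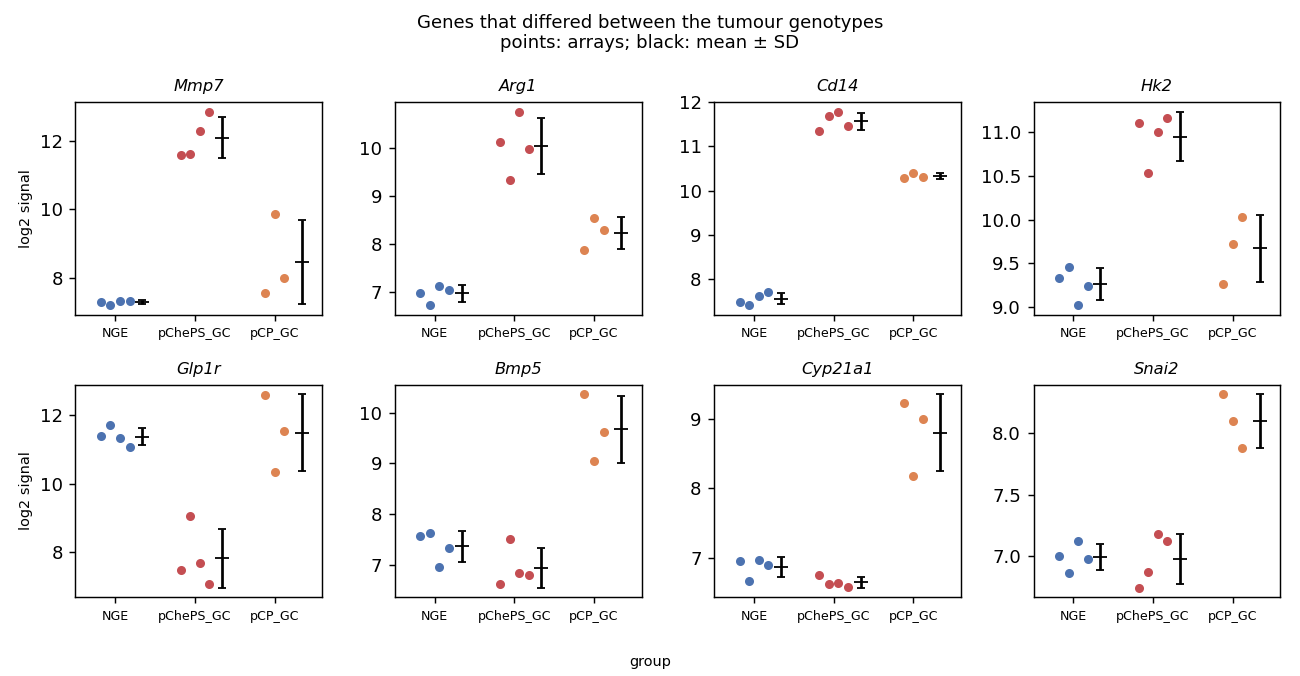
Log2 signal of 8 genes that passed between the tumour groups, on each array (points, coloured by group), with the group mean ± SD in black. Mmp7 was higher by 3.62 in pChePS_GC and Glp1r lower by 3.66.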

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

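The tests on sex-linked genes and on Cdh1 were chosen after the result was seen; those on dim genes and on other splits of the arrays were not, although the changes by signal level had been seen. Among 350 gene and group pairs, 15 (4.29%) held an array far from the other 3, and chance gives about 1 in 20. As gap over range, pChePS_GC replicate 2 stood high for Gsdma2 (0.951), Atp4b (0.958) and Ghrl (0.918) and low for Ptf1a (0.871). The other arrays were NGE replicate 4 for Cldn7 (0.841), NGE replicate 2 for Phlda3 (0.853), Mmp7 (0.847), Krt15 (0.838) and Vwf (0.884), NGE replicate 3 for Bbc3 (0.854), pChePS_GC replicate 1 for Cxcr2 (0.831) and Cxcl12 (0.847), pChePS_GC replicate 3 for Cxcl5 (0.915), and pChePS_GC replicate 4 for Gzma (0.933) and Chat (0.875).

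The change against NGE differed between tumour groups, by the limma test of that difference, for Pga5 (-1.93), Fabp2 (-1.82), Cd14 (1.24), Hk2 (1.28) and Mmp7 (3.62). That test is the comparison of pChePS_GC with pCP_GC given above, and each call was lost in at least 1 alternative (Pga5 in 15 of 20). Of the probe sets unnamed here, 123 in pChePS_GC and 149 in pCP_GC passed with a level at least 2-fold above NGE, and 291 and 177 with a level at least 2-fold below it.

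Xist was high and Y-linked genes low in all NGE arrays, and the reverse held in all tumour arrays. Lower Xist in tumours of female mice is argued against by the Y-linked genes, whose median change was 4.92 in pChePS_GC and 4.22 in pCP_GC. A mislabelled array is not tested by the count of 0 arrays with both the Xist and the Y-linked level of the other class. That count follows from the pattern itself, and a swap between the tumour groups, which carry like levels, would not show in it. Arrays out of place on either measure were counted first, which gave 1, pCP_GC replicate 3, and the count was then changed to both measures, as the test had been stated. The mean Y-linked level of that array lies under the midpoint of 8.26 but above the highest NGE level of 5.81, with Xist at 5.57. Sex as a source of the differences from NGE cannot be told apart from tumour, because 0 arrays allow a comparison within 1 sex.

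Many dim genes fell slightly in both tumour groups. A background or scaling difference may be the source: receptor genes fell with them, with medians of -0.15 in pChePS_GC and -0.22 in pCP_GC. Quantile normalization brought the 3988 dimmest genes to -0.033 and -0.039. It gives every array the same distribution, whatever the source of a shift, so it cannot tell sources apart. After it 5045 genes were called lower in pChePS_GC and 5432 in pCP_GC, against 4658 and 6343 in the main fit. A difference in tissue between epithelium and tumour stays open and was not tested.

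Cdh1 was not higher in tumours with 1 floxed allele. A lower share of epithelial cells in pChePS_GC as the whole source is argued against by the epithelial keratin and junction list, whose median between tumour groups was 0.15, with 0 of 20 genes as low as Cdh1. The surface mucous and mucous neck lists lay lower in pChePS_GC (medians of -0.87 and -0.63, adjusted p = 0.747 and 0.592 with an estimated correlation), so a lower share of these cell types stays open and was not tested. Whether the probe set reads a recombined allele cannot be told apart, since there is 1 probe set of unknown position. A difference by genotype stays open, since the difference of -1.60 did not pass (limma adjusted p = 0.183).

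The arrays of each comparison can be split in 35 ways. For pChePS_GC against NGE, 1 split, the real one, gave as many as 8386 genes (highest other 0 by limma), and for pCP_GC against NGE 1 gave as many as 10337 (highest other 5527, with NGE replicates 1, 3 and 4 against NGE replicate 2 and all pCP_GC arrays). In both, 1 of 35 is the smallest share these splits can give, which makes chance less likely but does not exclude it. Every other split puts tumour and NGE arrays together in a part, which widens the spread and favours few calls. For pChePS_GC against pCP_GC, 2 splits gave as many as the real 73 genes (highest other 82), so chance cannot be excluded. For lists, 2 splits gave as many as 22 (highest other 22), 11 as many as 20 (highest other 25) and 29 as many as 8 (highest other 20), in the same order of comparisons, shares at which chance cannot be excluded. For pChePS_GC against NGE the other split with 22 lists kept 3 arrays of each group together and so held part of the real contrast, while the 18 splits with 2 arrays of each group on either side gave 1 to 10. The 18 most even splits gave 6 to 22 lists for pCP_GC against NGE and 4 to 18 for pChePS_GC against pCP_GC.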

How the results depend on the processing

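Counts are given in the order genes changed, pChePS_GC against NGE, genes changed, pCP_GC against NGE, genes changed, pChePS_GC against pCP_GC, and genes changed in both tumour genotypes against NGE. The first pair stayed within 1.5 times under another variance prior, other scalings, the 25% filter, probe set summaries and array weights. Without the dimmest 50%, with fewer genes tested, they were 4881, 4611, 31 and 3716. At an adjusted p under 0.01 the first 3 were 4411, 6682 and 12, and at least 2-fold all were 2057, 2185, 42 and 1628. Between tumours 0 genes passed with only 2 groups fitted and 188 with array weights, which also gave 13 lists (the cause was not tested). With an estimated correlation 0, 0 and 0 lists passed, and camera on ranks kept each count of lists within 1.5 times. With the 6 splits of the controls 3381, 4758, 4067, 3528, 3410 and 4422 genes passed in both, with fewer arrays. With replicate number as a block, limma gave 8553, 9610 and 0 genes (3263 of the last at an unadjusted p under 0.05), and the immune checkpoint list, pCP_GC against NGE, passed (adjusted p = 0.039, range 0.0201 to 0.139). Same-numbered deviations correlated at -0.155 to 0.156 over 10 pairs and 3 arrays correlated best with their own number, which gave no sign that the numbers pair samples. Leaving out each array gave 6107 to 8773, 8344 to 10627, 26 to 154 and 4958 to 7360 genes, r of 0.889 to 0.920, and 21 to 23, 19 to 22 and 8 to 14 lists. The median of the fibroblast and collagen matrix list, pChePS_GC against pCP_GC, ran from -0.21 without pCP_GC replicate 1 to 0.43 without pCP_GC replicate 2, where its test turned up (adjusted p = 0.0389, range 0.0389 to 0.966, the cause was not tested). Of the 22, 20 and 8 called lists, 16, 15 and 5 held under every alternative run for single lists except the estimated correlation, as did 103 of 115, 98 of 114 and 0 of 16 named genes. Lists and genes that a filter on dim genes removed were not tested under that filter, and could count as held. Without the dimmest 50% of genes, 211 of 281 pairs of named gene and comparison were left. Dim genes near background limit what small changes can show.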

Other observations

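Gene families were chosen by name after their values were seen; 8 were examined, and some members, Cldn4 and Cldn7 among those named here, are also in the fixed lists. Insulin-like growth factor binding proteins went apart: of 7 members 4 rose and 2 fell in each tumour group. Igfbp3, Igfbp4, Igfbp5 and Igfbp7 rose in pChePS_GC (4.19, 4.21, 3.04 and 4.32, limma adjusted p at most 0.00016) and in pCP_GC (3.29, 4.52, 4.01 and 4.42). Of those that fell, Igfbp2 did so by 1.56 and by 2.42. The acute-phase gene Saa3 rose by 3.80 and 4.90, and Reg1 rose by 4.66 and 3.23. Of 8 gasdermins 6 fell in pChePS_GC and 5 in pCP_GC, while Gsdmd, a gasdermin that forms pores in pyroptosis, rose by 1.03 in pChePS_GC. The directions of the genes named here held with quantile normalization and with centred arrays. Among the gasdermins that moved, Gsdmc in pChePS_GC lost its call after quantile normalization (adjusted p = 0.0838), and Gsdme, which rose by 0.42 in pCP_GC, lost it with centred arrays (adjusted p = 0.133). Saa2 fell by 0.30 in pCP_GC and lost its call after quantile normalization (adjusted p = 0.479).

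Of 23 claudins, which form tight junctions, 6 rose and 3 fell in pChePS_GC and 4 rose and 8 fell in pCP_GC. The falls numbered 6 and 4 after quantile normalization and 12 and 11 with centred arrays, so neither tumour group had more of them under every scaling. Cldn2, Cldn4, Cldn6 and Cldn7 rose in both tumour groups (3.46, 3.25, 2.27 and 3.57 in pChePS_GC, and 4.20, 2.36, 2.89 and 3.40 in pCP_GC) and Cldn8 fell (-1.61 and -1.75), with the same directions under both scalings. Of 57 ribosomal protein genes 37 rose and 1 fell in pChePS_GC, with a median of 0.43 (0.25 with centred arrays, where 25 rose and 3 fell). In pCP_GC 27 rose and 2 fell, with a median of 0.28, while with centred arrays 3 rose and 5 fell, with a median of 0.063. Between tumour groups Rps14 (0.58) and Rps9 (0.50) passed (adjusted p = 0.0435 and 0.0455), and did not with centred arrays (adjusted p = 0.0702 and 0.0711). Of 37 Hox genes 23 fell in pCP_GC, with a median of -0.37 (-0.20 after quantile normalization, where 10 of the 23 kept their call, and -0.58 with centred arrays, where 28 fell). In pChePS_GC 7 fell, with a median of -0.17 (-0.093 after quantile normalization, where 7 fell, and -0.34 with centred arrays, where 24 fell). Hoxa5 rose in both (0.72 in pChePS_GC, adjusted p = 0.01, and 0.92 in pCP_GC, adjusted p = 0.00327) and passed under both scalings. Of 4 metallothioneins Mt3 and Mt4 fell in both groups, where Mt4 in pChePS_GC lost its call after quantile normalization (adjusted p = 0.0647).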
